A study of Rattus norvegicus with 8 samples.

How the data were processed

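miRNA sequencing of rat BMSCs was analysed in 8 samples, 4 control and 4 treated with 10 µM dexamethasone for 48 h, grouped by the sample titles. Per the labels' protocols, total RNA was taken with a Qiagen miRNA kit and libraries were made with a VAHTS total RNA kit for Illumina, although the series and its table are of miRNAs. Whether a small RNA kit was used, how short RNAs were selected and whether the kit marks strand are not given in the sources used here. Library preparation can capture some miRNAs better than others, so ranks of abundance are ranks of counts, not of molecules. The submitters' processing notes name Bowtie 1.0 and the genome build mRatBN7.2. The counter, the miRNA annotation release and the treatment of reads that match several miRNAs are not given in the sources used here, so near-identical family members (let-7, miR-29, miR-30, miR-101 and others) are uncertain individually.

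The deposited table holds whole-number counts for 487 mature miRNAs, all with rat miRBase names, with 1 column per sample. The authors' CPM columns were checked and equal each count divided by the column total and scaled, to within 4.98e-05. Per the file headers the table also gives mean CPM per group, a log2 fold change, a p-value and an adjusted p-value. The authors' log2 fold change was checked and equals the log2 ratio of the mean CPM plus 1. The test behind the authors' p-value is not given in the sources used here. Differential tests used the counts, and CPM serve as levels in the text.

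Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test, group as the only term, Benjamini-Hochberg adjustment, threshold 0.05). The filter kept 245 miRNAs, and the 242 others held at most 0.0332% of a sample's counts. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. TMM factors ran from 0.944 to 1.02 and the biological coefficient of variation was 10.4%. Within groups the chi-square per degree of freedom between pairs of libraries, over miRNAs with at least 10 counts, was 7.56 to 48.6, so no pair differed by as little as sampling noise.

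Single values (library size, detected miRNAs, share of the 10 most abundant) were compared with exact two-sided permutation tests over 70 assignments. Fixed lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and fry as alternatives, adjusted over the 19 of 22 lists with at least 3 tested members. The lists were miR-17~92 and paralogs, let-7, Dlk1-Dio3, miR-322 and miR-503, miR-15 and miR-16, miR-23, miR-27 and miR-24, miR-29, miR-30, miR-34 and miR-449, miR-181, miR-221 and miR-222, mesenchymal and pericyte, glucocorticoid-linked, pro- and anti-osteogenic, pro- and anti-adipogenic, and markers of haematopoietic, endothelial and erythroid, muscle, epithelial and neural cells; all mature arms of a listed name counted. fry tests whether a list's members move on balance 1 way and does not compare the list with other miRNAs. The ratio of 5p to 3p was tested with limma on log2 CPM (prior 1) in 53 hairpins with both arms tested.

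The miRNAs named were set by a rule: the 8 with the largest fold change in each direction among those past the threshold with a mean of at least 10 CPM and no overlap between groups, the 4 with the smallest p in each direction, the 6 most abundant, and up to 3 most abundant tested members of each list, 65 in all. Members named beyond these, such as miR-449a-5p, miR-449c-5p, miR-450a-5p, miR-708-5p, miR-142-3p and the arms of miR-455, miR-210 and miR-140, were chosen after their values were seen. Lists, rule, tests and alternatives were fixed before the data were examined, and the text says where a test was added later.

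On simulated counts for the same libraries with known changes, with 243 miRNAs tested for dexamethasone against control, edgeR recovered 84.8% of miRNAs changed 1.5-fold, 97.4% of those changed 2-fold and 100% of those changed 4-fold, and 1.94% of its calls were false. camera and the arm ratio test each found the single planted change and called 0 with nothing changed. The simulated miRNAs were drawn independently of each other, so the 0 list calls do not cover false calls from correlation among list members. Alternatives were RLE size factors in edgeR (the scaling method of DESeq2), upper quartile scaling, total counts, the DESeq2 1.42.0 Wald test and limma voom. Others were no filter, a filter of 10 CPM in at least 4 samples, thinning to 1377881 counts and library sizes without the 10 most abundant miRNAs. A replicate block, a threshold of 0.1 and leaving out each replicate were also run. Gene neighbourhoods were read from RefSeq names on the assembly GRCr8, which is not the build of the files, so no coordinates are given; 224 of 245 tested miRNAs matched a single gene.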

Results

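miRNA sequencing libraries from rat bone marrow mesenchymal stem cells (BMSCs), the plastic-adherent stromal cells of marrow that can form bone, cartilage and fat cells, were compared with and without dexamethasone, a synthetic glucocorticoid. There were 4 control samples and 4 samples treated with 10 µM dexamethasone for 48 h, and the series asked how miRNA levels change under this treatment. The library kit the labels name is one for total RNA, and whether a small RNA kit was used is not given in the sources used here. The deposited table listed 487 mature miRNAs. Total counts were 2639007, 2348575, 1835256 and 2224941 in control replicates 1 to 4 and 1448787, 1521505, 1421235 and 1377881 in dexamethasone replicates 1 to 4. The mean was 2261945 ± 333223 counts in control and 1442352 ± 60302 in dexamethasone samples (SD, n = 4 each), and every treated library was shallower than every control library (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). A count of 0 in a sample allowed 3 counts, or 1.14 to 2.18 CPM, a limit that covers counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which can be technical.

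The libraries separated by treatment. The first principal component held 62.6% of the variance and parted the 4 control from the 4 dexamethasone samples, and the second held 13.5%. Spearman correlations of log2 CPM ran from 0.989 to 0.992 among controls, from 0.977 to 0.990 among treated samples and from 0.961 to 0.969 between the groups. The 10 most abundant miRNAs took 83.3 ± 0.296% of counts in control and 84.0 ± 0.269% in dexamethasone samples (SD, n = 4, exact two-sided permutation p = 0.0286). At least 1 count was found for 386 ± 5.48 miRNAs per control and 377 ± 7.85 per treated sample (SD, n = 4), which did not pass the exact two-sided permutation test (p = 0.114).

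Among miRNAs with a mean of at least 10 CPM, miR-672-5p and miR-1b showed the largest rises after dexamethasone. rno-miR-672-5p rose 5.20-fold, from 20.0 ± 2.06 to 102 ± 19.3 CPM (SD, n = 4), with a log2 fold change of 2.38 ± 0.17 (SE, edgeR adjusted p = 2.68e-07). rno-miR-101b-3p, of the family known for targeting the histone methyltransferase Ezh2, rose 3.3-fold, from 65.8 ± 5.13 to 213 ± 11.5 CPM (SD, n = 4, edgeR adjusted p = 2.99e-08). rno-miR-224-5p rose 2.73-fold, from 298 ± 5.88 to 801 ± 93.7 CPM (SD, n = 4, edgeR adjusted p = 3.19e-08). The skeletal muscle miRNA rno-miR-206-3p rose from 80.0 ± 15.3 to 235 ± 39.4 CPM and rno-miR-1b from 6.34 ± 0.783 to 25.5 ± 6.51 CPM, with log2 fold changes of 1.58 ± 0.16 and 2.01 ± 0.24 (SD and SE, n = 4; edgeR adjusted p = 8.75e-06 and 2.33e-05). Smaller rises were seen for miR-187-3p (1.16 ± 0.22), miR-503-5p (1.15 ± 0.11), miR-532-5p (1.06 ± 0.12) and miR-351-5p (0.94 ± 0.07, log2 fold change ± SE), with edgeR adjusted p between 6.62e-07 and 0.00106. In each of these miRNAs all 4 treated samples lay above all 4 controls.

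The largest falls among them were in miR-146a-5p and both arms of miR-132. rno-miR-146a-5p, an NF-κB-induced miRNA that restrains Toll-like receptor signalling, fell from 4704 ± 357 to 1355 ± 55.6 CPM (SD, n = 4), 3.41-fold lower with the smallest p of the 245 tested (log2 fold change -1.77 ± 0.06, SE, edgeR adjusted p = 4.63e-10). Both arms of miR-132 and of miR-212, which share a CREB-responsive primary transcript, fell. rno-miR-132-3p went from 3247 ± 181 to 1195 ± 313 CPM and rno-miR-132-5p from 241 ± 19.6 to 82.9 ± 12.4 CPM (SD, n = 4), with log2 fold changes of -1.42 ± 0.14 and -1.51 ± 0.11 (SE, edgeR adjusted p = 7.20e-06 and 2.68e-07). For rno-miR-212-3p and rno-miR-212-5p the log2 fold changes were -1.27 ± 0.21 and -1.11 ± 0.14 (SE, edgeR adjusted p = 4.36e-04 and 3.54e-05). rno-miR-31a-5p fell from 12119 ± 629 to 5794 ± 442 CPM (SD, n = 4, log2 fold change -1.04 ± 0.06, SE, edgeR adjusted p = 5.06e-08). rno-miR-671 and rno-miR-148a-5p fell too, with log2 fold changes of -1.36 ± 0.23 and -1.26 ± 0.13 (SE, edgeR adjusted p = 4.52e-04 and 1.03e-05).

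**Figure D1:**
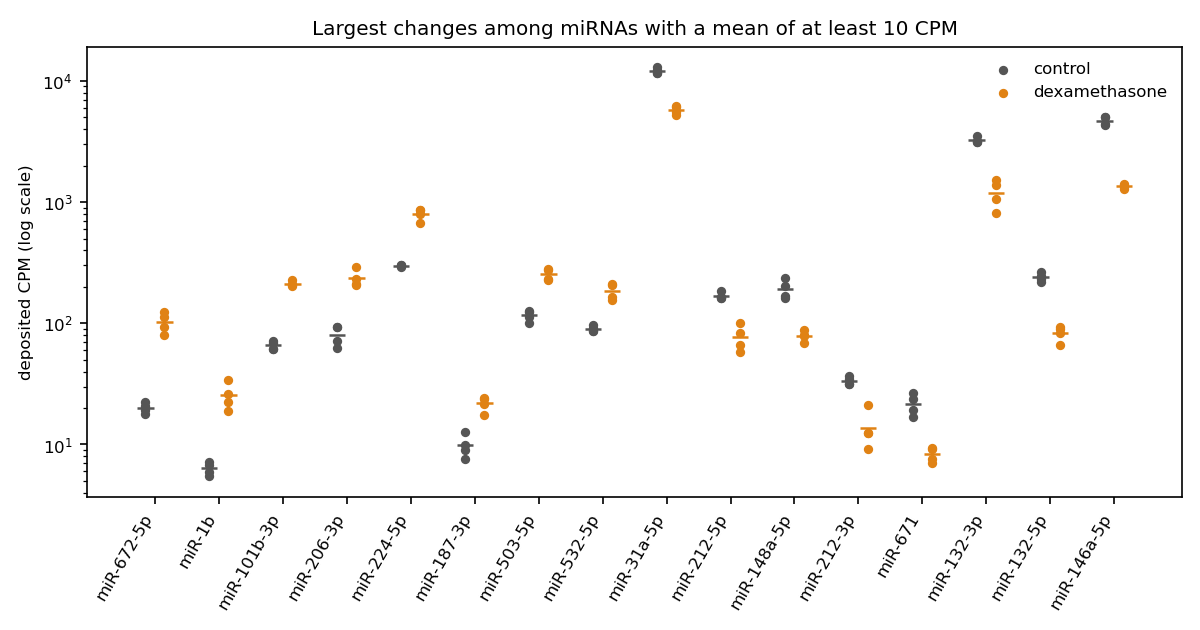
CPM as deposited (log axis) of the 8 miRNAs with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 10 CPM and no overlap between groups, in the 4 control (grey) and 4 dexamethasone (orange) samples. Points are samples and bars are group means; the 4 treated samples lie on 1 side of the 4 controls for each miRNA, as for miR-146a-5p with means of 4704 and 1355 CPM.

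Over all 245 miRNAs that passed the abundance filter, 61 were higher and 52 lower after dexamethasone at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p below 0.05, and 132 did not pass. Of the 113 that passed, 65 changed at least 1.5-fold (34 higher, 31 lower), and 13 rose and 10 fell at least 2-fold. The median size of the log2 fold change among the 113 was 0.64. The groups did not overlap in 103 tested miRNAs (42.0%), where chance gives 2.86%. With upper quartile scaling, which moved the median log2 fold change by -0.15, 41 were higher and 71 lower (36.6% of calls higher against 54.0% in the TMM fit), so the balance of rises and falls depends on the scaling. Depth and treatment were confounded, as every treated library was shallower, and the labels give no batch. The labels used here also give no time in culture or vehicle for the controls.

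**Figure D2:**
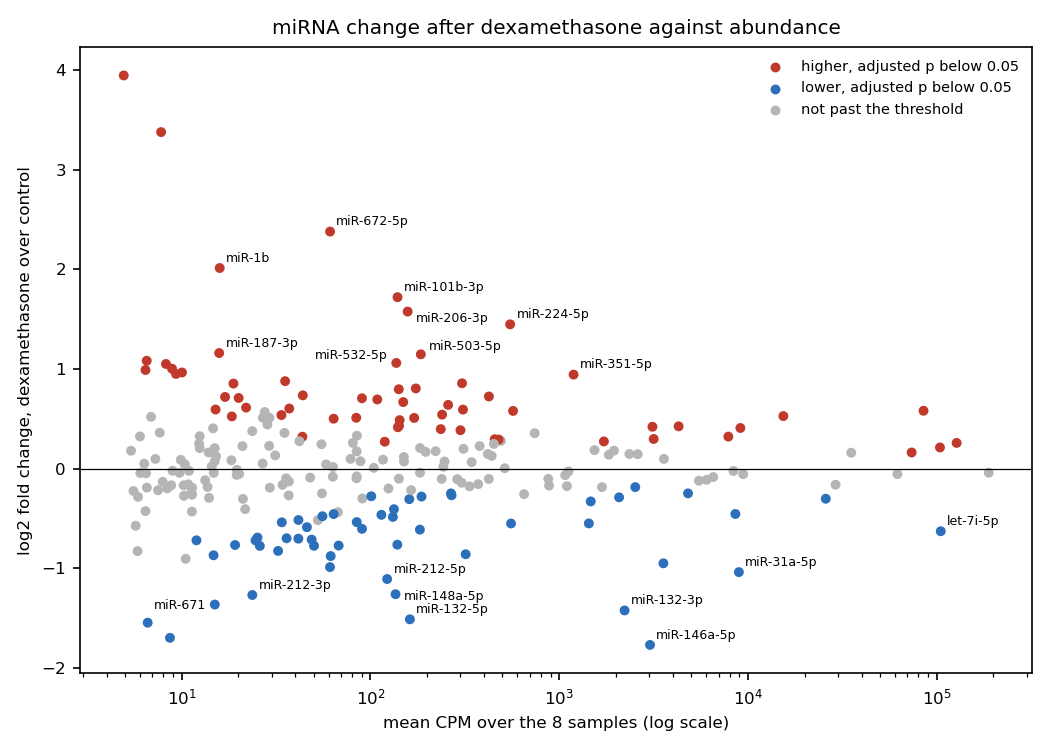
Log2 fold change of dexamethasone over control against mean CPM (log axis) for the 245 tested miRNAs, with 61 higher (red), 52 lower (blue) and 132 that did not pass (grey) at an edgeR adjusted p below 0.05. Changes span the abundance range, as in miR-672-5p (2.38), miR-146a-5p (-1.77) and let-7i-5p (-0.63); under upper quartile scaling 41 were higher and 71 lower.

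Among the 6 most abundant miRNAs, let-7i-5p fell and miR-21-5p rose. rno-let-7i-5p went from 128677 ± 2133 to 81615 ± 4864 CPM and rno-miR-21-5p, an miRNA of proliferating and fibrotic tissue, from 68956 ± 3581 to 101442 ± 11629 CPM (SD, n = 4), with log2 fold changes of -0.63 ± 0.06 and 0.58 ± 0.06 (SE, edgeR adjusted p = 5.44e-06 and 1.29e-05). rno-miR-125b-5p and rno-miR-199a-3p rose by less, with log2 fold changes of 0.26 ± 0.06 and 0.21 ± 0.03 (SE, edgeR adjusted p = 0.00329 and 3.44e-04); with upper quartile scaling both missed the threshold, at 0.11 and 0.06 (edgeR adjusted p = 0.231 and 0.415). rno-miR-16-5p, the most abundant of all with 193157 ± 4462 CPM in control and 184413 ± 5239 CPM in treated samples, did not pass (log2 fold change -0.04 ± 0.04, SE, edgeR adjusted p = 0.401), but upper quartile scaling put it at -0.19 (edgeR adjusted p = 0.011). rno-let-7f-5p was at the threshold (0.16 ± 0.06, SE, edgeR adjusted p = 0.0436). It was lost with RLE size factors in edgeR (adjusted p = 0.108) and without any 1 of 7 replicates, all but dexamethasone replicate 4 (edgeR adjusted p = 0.051 to 0.202). Its log2 fold change was 0.10 without dexamethasone replicate 1 and 0.01 with upper quartile scaling.

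The 9 tested arms of the X-linked cluster of miR-322 and miR-503, whose members target cell cycle genes, all rose. rno-miR-503-5p went from 116 ± 11.9 to 254 ± 28.0 CPM, rno-miR-351-5p from 826 ± 32.7 to 1559 ± 96.0 CPM and rno-miR-542-3p from 221 ± 15.9 to 391 ± 30.3 CPM (SD, n = 4), and rno-miR-322-5p from 1580 ± 63.7 to 1871 ± 125 CPM, the smallest rise (log2 fold change 0.27 ± 0.07, SE, edgeR adjusted p = 0.00803). The counts adjusted over the list alone were 9 higher and 0 lower. camera gave the cluster an adjusted p of 0.00111 over 19 lists, and adjusted p = 0.180 with an estimated correlation. Across the alternatives 6 to 9 of the arms were higher and 0 lower; 6 were higher without control replicate 1 and 7 with upper quartile scaling. In those fits miR-322-5p missed the threshold (edgeR adjusted p = 0.0535 and 0.267). rno-miR-450a-5p was at the threshold (0.61 ± 0.23, log2 fold change, SE, edgeR adjusted p = 0.0444). It missed it without control replicate 1, 2 or 3 or dexamethasone replicate 1, 2 or 3 (edgeR adjusted p = 0.058 to 0.135).

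The Dlk1-Dio3 imprinted cluster, a large maternally expressed miRNA locus, held falls and no rise. Of 17 tested arms, 8 fell and 0 rose (9 and 0 adjusted over the list alone), and all 17 log2 fold changes were below 0, from -1.54 to -0.04. rno-miR-127-3p and rno-miR-379-5p fell, with log2 fold changes of -0.46 ± 0.12 and -0.28 ± 0.08 (SE, edgeR adjusted p = 0.00665 and 0.00983). rno-miR-541-5p was at the threshold (-0.28 ± 0.10, SE, edgeR adjusted p = 0.0436) and lost its call with DESeq2 (adjusted p = 0.0556) and without control replicate 1, 2 or 3 or dexamethasone replicate 1, 2 or 3 (edgeR adjusted p = 0.0538 to 0.0992). camera gave the cluster an adjusted p of 0.0308, and adjusted p = 0.180 with an estimated correlation; without dexamethasone replicate 4 the camera adjusted p was 0.0610.

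In the p53-linked miR-34 and miR-449 family 4 of 6 tested arms fell and 0 rose (5 and 0 adjusted over the list alone), and miR-34a-5p and miR-34b-5p did not pass over all miRNAs. miR-34b-5p fell without control replicate 1 or 4 (edgeR adjusted p = 0.0487 and 0.0179) and with upper quartile scaling (0.021). Another member, miR-449c-5p, was left out by the abundance filter and went the other way, with 2 counts over the 4 controls and 12 over the 4 treated samples. With no filter it was higher (edgeR adjusted p = 0.0299), giving 1 higher and 5 lower among 10 arms. It was also higher in the authors' deposited table (adjusted p = 0.0262). rno-miR-449a-5p fell from 81.7 ± 6.32 to 40.4 ± 4.16 CPM, rno-miR-34c-5p from 665 ± 14.9 to 446 ± 34.0 CPM and rno-miR-34b-3p from 85.9 ± 9.78 to 49.8 ± 14.2 CPM (SD, n = 4), with log2 fold changes of -0.99 ± 0.11, -0.55 ± 0.07 and -0.77 ± 0.17 (SE, edgeR adjusted p = 1.70e-05, 2.86e-05 and 0.00339). rno-miR-34a-5p had 339 ± 22.3 CPM in control and 348 ± 30.1 CPM in treated samples (log2 fold change 0.07 ± 0.09, SE, edgeR adjusted p = 0.583). The camera adjusted p was 0.0455, and adjusted p = 0.349 with an estimated correlation. It missed the threshold without control replicate 3 (camera adjusted p = 0.0797), dexamethasone replicate 1 (0.0733) or dexamethasone replicate 4 (0.0610).

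In the miR-30 family 6 of 11 tested arms rose and 0 fell, over all miRNAs and adjusted over the list alone. rno-miR-30a-5p went from 128 ± 13.8 to 219.7 ± 16.7 CPM and rno-miR-30d-5p from 462 ± 31.1 to 678 ± 51.4 CPM (SD, n = 4, edgeR adjusted p = 3.88e-05 and 5.39e-05), and rno-miR-30a-3p rose with a log2 fold change of 0.49 ± 0.10 (SE, edgeR adjusted p = 0.00209). As a list against other miRNAs the family did not pass (camera adjusted p = 0.108). In the miR-29 family, known for repressing collagen and other matrix transcripts, 2 of 3 tested arms rose, rno-miR-29a-3p from 12765 ± 868 to 18056 ± 2148 CPM and rno-miR-29b-3p from 3704 ± 166 to 4885 ± 383 CPM (SD, n = 4, edgeR adjusted p = 1.49e-04 and 7.68e-05), with the same count adjusted over the list alone; rno-miR-29c-3p was at 0.09 ± 0.15 (log2 fold change, SE, edgeR adjusted p = 0.66). The list did not pass (camera adjusted p = 0.258).

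From the cluster of miR-221 and miR-222, known for repressing cell cycle inhibitors, rno-miR-221-3p fell from 4725 ± 203 to 2408 ± 405 CPM (SD, n = 4, log2 fold change -0.95 ± 0.09, SE, edgeR adjusted p = 7.20e-06). Its neighbour rno-miR-222-3p was at -0.44 ± 0.20 and rno-miR-221-5p at 0.02 ± 0.28 (log2 fold change, SE, edgeR adjusted p = 0.0929 and 0.955), so 1 of 3 arms fell, also adjusted over the list alone (camera adjusted p = 0.304). miR-222-3p fell with DESeq2 (adjusted p = 0.0358), with upper quartile scaling (edgeR adjusted p = 0.02) and without control replicate 4 (0.0481) or dexamethasone replicate 4 (0.00228). Its log2 fold change was -0.68 without dexamethasone replicate 4.

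In the let-7 family let-7i-5p fell, while most of its relatives did not pass. Of 15 tested arms 1 rose and 2 fell (0 and 1 adjusted over the list alone), the falls being let-7i-5p and the low-abundance let-7c-1-3p (-0.72 ± 0.26, SE, edgeR adjusted p = 0.0415). rno-let-7c-5p, the next most abundant member after let-7i-5p and let-7f-5p, had 63725 ± 2306 CPM in control and 60159 ± 3895 CPM in treated samples (SD, n = 4, edgeR adjusted p = 0.555, but 0.0434 without dexamethasone replicate 1 and 0.0418 with upper quartile scaling). The summed CPM of the other 8 let-7 5p arms was 210834 ± 4365 in control and 213237 ± 13666 in treated samples (SD, n = 4, exact two-sided permutation p = 0.914). Members differ by few bases, so counts can be shared between them, depending on how the authors counted. The list did not pass (camera adjusted p = 0.817), and its counts depended on the fit. With upper quartile scaling 0 arms rose and 6 fell. The counts were 1 and 5 without dexamethasone replicate 1, 4 and 1 without dexamethasone replicate 4, 1 and 1 without dexamethasone replicate 2, 0 and 2 without control replicate 1 or dexamethasone replicate 3, and 0 and 1 without control replicate 2, 3 or 4. let-7i-5p was lower in each of these fits. let-7c-1-3p missed the threshold without control replicate 2, 3 or 4 or dexamethasone replicate 2 or 4 (edgeR adjusted p = 0.0519 to 0.104).

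In the other families few arms passed. In miR-17~92 and its paralogs 2 of 13 tested arms rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.835); the rises were miR-19a-3p (0.59 ± 0.20) and miR-19b-3p (0.27 ± 0.09, log2 fold change ± SE), both near the threshold (edgeR adjusted p = 0.0311 and 0.0313). Neither passed with upper quartile scaling, the DESeq2 Wald test, no filter or the replicate block. Without control replicate 1, 2 or 3 there were 0 higher arms, and without dexamethasone replicate 1, 2 or 3 there was 1. Without dexamethasone replicate 4 there were 2 higher and 2 lower, the falls being miR-18a-5p and miR-92a-1-5p (edgeR adjusted p = 0.0191 and 0.0421). The abundant rno-miR-25-3p, rno-miR-93-5p and rno-miR-20a-5p were at 0.10 ± 0.05, 0.15 ± 0.06 and -0.10 ± 0.11 (log2 fold change, SE, edgeR adjusted p = 0.159, 0.0536 and 0.496). miR-93-5p passed without dexamethasone replicate 1 or 4 (edgeR adjusted p = 0.0381 and 0.0365). In the miR-15 and miR-16 family 1 of 5 arms fell, miR-497-5p (-0.70 ± 0.18, SE, edgeR adjusted p = 0.00644), with the same count adjusted over the list alone (camera adjusted p = 0.817). rno-miR-15b-5p was at 0.00 ± 0.08 and rno-miR-195-5p at 0.17 ± 0.12 (log2 fold change, SE, edgeR adjusted p = 0.959 and 0.251). A second arm, miR-195-3p, passed the filter and fell without control replicate 1 or any 1 dexamethasone replicate (edgeR adjusted p = 0.00346 to 0.0376). In the miR-23, miR-27 and miR-24 clusters 1 of 7 arms rose, miR-23b-3p (0.29 ± 0.08, SE, edgeR adjusted p = 0.0113; 1 adjusted over the list alone; camera adjusted p = 0.986). rno-miR-27b-3p, rno-miR-24-3p and rno-miR-23a-3p were at -0.11 ± 0.05, -0.12 ± 0.06 and 0.14 ± 0.07 (log2 fold change, SE, edgeR adjusted p = 0.0758, 0.0944 and 0.122); with upper quartile scaling miR-27b-3p and miR-24-3p fell, at -0.26 and -0.27 (edgeR adjusted p = 0.00276 and 0.00445). miR-23b-3p missed the threshold without control replicate 1 or 2 (edgeR adjusted p = 0.0538 and 0.0609) and with upper quartile scaling (0.249). miR-24-3p also fell without dexamethasone replicate 4 (edgeR adjusted p = 0.0493), and miR-23a-3p and miR-27a-5p rose without dexamethasone replicate 1 (0.0353 and 0.0437). In the miR-181 family 1 of 5 arms fell, rno-miR-181a-1-3p (from 63.9 ± 12.6 to 36.6 ± 5.84 CPM, SD, n = 4, edgeR adjusted p = 0.00196), with 1 adjusted over the list alone (camera adjusted p = 0.817), while rno-miR-181a-5p and rno-miR-181b-5p were at 0.36 ± 0.20 and 0.18 ± 0.23 (log2 fold change, SE, edgeR adjusted p = 0.173 and 0.586). Without dexamethasone replicate 1 miR-181a-5p rose, at 0.53 (edgeR adjusted p = 0.00537), and miR-181c-5p, otherwise under the filter, rose without any 1 dexamethasone replicate (0.00163 to 0.0119). With upper quartile scaling the list medians of miR-17~92 (0.09), miR-23, miR-27 and miR-24 (0.14) and miR-181 (0.05) were -0.06, -0.01 and -0.10, and they changed sign under 2, 7 and 7 alternatives in all. The miR-181 list had a positive median and a negative mean (-0.05) and camera direction.

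Among miRNAs described as promoting osteoblast differentiation 6 of 11 tested arms rose and 2 fell, with the same counts adjusted over the list alone. rno-miR-21-5p, rno-miR-26a-5p and rno-miR-29b-3p rose, miR-26a-5p from 7916 ± 282 to 10326 ± 1172 CPM (SD, n = 4, log2 fold change 0.41 ± 0.07, SE, edgeR adjusted p = 3.67e-04), and miR-218a-5p rose from 69.5 ± 9.98 to 111 ± 24.3 CPM. The falls were both arms of the hypoxia-induced miR-210 (-0.31 ± 0.11 for miR-210-3p and -0.87 ± 0.24 for miR-210-5p, log2 fold change ± SE, edgeR adjusted p = 0.0444 and 0.00983). miR-210-3p missed the threshold without control replicate 1, 3 or 4 or dexamethasone replicate 1, 2 or 4 (edgeR adjusted p = 0.0527 to 0.115), after thinning and with the replicate block (0.068 and 0.0644). This left 1 fall. Without dexamethasone replicate 4 its log2 fold change was -0.19. Among the rises miR-335 was at the threshold (0.74 ± 0.28, log2 fold change ± SE, edgeR adjusted p = 0.0444). It missed the threshold without any 1 control replicate (edgeR adjusted p = 0.0535 to 0.0786). Without dexamethasone replicate 1 its log2 fold change was 0.31 (edgeR adjusted p = 0.163). The list had 4 rises without control replicate 1. As a list it did not pass (camera adjusted p = 0.261). Among miRNAs described as restraining osteoblast differentiation 5 of 24 tested arms rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.366). The falls included miR-31a-5p, miR-221-3p and miR-34c-5p, and the rises miR-206-3p, miR-125b-5p and rno-miR-103-3p (0.30 ± 0.06, SE, edgeR adjusted p = 0.00194; 0.121 with upper quartile scaling). With upper quartile scaling 4 and 2 of the first list and 3 and 11 of the second were higher and lower. Counted by miRNA name without the arm, 4 tested members of the first list and 15 of the second stand on other lists too. Counted by arm the overlap is larger.

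The adipocyte lists were mixed. Among miRNAs described as promoting adipocyte differentiation 5 of 16 tested arms rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.817). The rises were miR-21-5p, miR-30a-5p, miR-30a-3p, miR-30d-5p and miR-103-3p. The falls included rno-miR-143-3p, an abundant smooth muscle and stromal miRNA, which went from 28820 ± 605 to 22893 ± 2075 CPM (SD, n = 4, edgeR adjusted p = 0.00525). The other falls were less abundant arms: miR-143-5p (mean 55.8 to 36.4 CPM), miR-148a-5p (193 to 78.9 CPM) and miR-211-5p (13.3 to 4.01 CPM). miR-148a-3p, the more abundant arm of its hairpin, did not pass (log2 fold change 0.28, edgeR adjusted p = 0.0781). Arms of the same hairpin were counted separately. The list's median was above 0 (0.09) and its mean below (-0.05), with a camera direction above 0, and the median was -0.07 with upper quartile scaling. Among those described as restraining adipocyte differentiation 2 of 12 rose, miR-224-5p and miR-155-5p, and 2 fell, both arms of miR-31a, also adjusted over the list alone (camera adjusted p = 0.817). With upper quartile scaling 1 was higher and 3 lower. By miRNA name without the arm, 7 and 6 tested members of these lists stand on other lists too, and more do when counted by arm.

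The glucocorticoid list held miRNAs linked to such treatment, in either direction, by earlier work in other cells. Of its 25 tested arms 6 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.863). camera looks for a shared direction, so it cannot show whether a list expected to go both ways responds. The rises were both arms of miR-199a, miR-21-5p, miR-29a-3p, miR-19a-3p and miR-19b-3p. The falls were rno-miR-708-5p, from 415 ± 19.2 to 225 ± 27.2 CPM (SD, n = 4, log2 fold change -0.86 ± 0.09, SE, edgeR adjusted p = 7.58e-06), and both arms of miR-455 (-0.61 ± 0.09 for the 5p and -0.72 ± 0.17 for the 3p arm, log2 fold change ± SE). The list's median was 0.05 and its mean -0.00238, with a camera direction above 0, and the median was -0.10 with upper quartile scaling. That scaling gave 3 higher and 4 lower, which turned the balance of the counts. Without dexamethasone replicate 4 there were 5 higher and 5 lower. miR-19a-3p and miR-19b-3p missed the threshold with upper quartile scaling and without control replicate 1, 2 or 3 or dexamethasone replicate 1 (edgeR adjusted p = 0.0676 to 0.415). By miRNA name without the arm, 15 tested members stand on other lists too, and more do when counted by arm. Of the mesenchymal and pericyte miRNAs, abundant in cultured stromal cells, 5 of 23 tested arms rose, among them miR-199a-3p, miR-125b-5p and miR-21-5p, and 6 fell, among them miR-31a-5p and miR-143-3p (same counts adjusted over the list alone; camera adjusted p = 0.615); with upper quartile scaling 3 were higher and 10 lower.

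Markers of other cell types moved in both directions. Of 5 tested haematopoietic markers 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.817). rno-miR-155-5p rose from 413 ± 16.8 to 498 ± 20.0 CPM and miR-142-3p from 27.8 ± 1.26 to 39.8 ± 3.78 CPM (SD, n = 4, edgeR adjusted p = 0.00426 and 0.00479), while miR-146a-5p and rno-miR-146b-5p fell, the second from 1652 ± 81.1 to 1287 ± 214 CPM (SD, n = 4, edgeR adjusted p = 0.0343). miR-146b-5p missed the threshold without control replicate 2 or 4 or dexamethasone replicate 2, 3 or 4 (edgeR adjusted p = 0.0523 to 0.0722). miR-155-5p missed the threshold with upper quartile scaling (edgeR adjusted p = 0.172). Both arms of the endothelial miR-126a fell, rno-miR-126a-3p from 1721 ± 91.1 to 1153 ± 56.1 CPM and rno-miR-126a-5p from 153 ± 5.96 to 113 ± 16.5 CPM (SD, n = 4, edgeR adjusted p = 3.54e-05 and 0.0119), and these were the 2 tested endothelial and erythroid markers. Both tested muscle markers rose, miR-206-3p and the low-abundance rno-miR-499-5p (from 6.84 ± 1.48 to 13.2 ± 4.36 CPM, SD, n = 4, edgeR adjusted p = 0.0169, and 0.0501 without control replicate 2). The single tested epithelial marker, rno-miR-203a-3p, was at 0.36 ± 0.38 (log2 fold change, SE, edgeR adjusted p = 0.483). The value depended on single libraries, with 0.63 without dexamethasone replicate 4, 0.57 without control replicate 3, 0.19 without dexamethasone replicate 3 and 0.18 without replicate 2 of either group. Of 3 neural markers 1 fell, rno-miR-129-5p (from 101 ± 3.22 to 68.5 ± 12.5 CPM, SD, n = 4, edgeR adjusted p = 0.003; camera adjusted p = 0.914 for the list, with a median of 0.23 and a mean of -0.03), and rno-miR-128-3p and rno-miR-9a-5p were both at 0.23 (log2 fold change; edgeR adjusted p = 0.0781 and 0.513). Without dexamethasone replicate 4 miR-128-3p rose and miR-128-1-5p, otherwise under the filter, fell (edgeR adjusted p = 0.00585 and 0.017). The list's median changed sign under 5 alternatives, at -0.55 with no filter and -0.15, -0.24, -0.18 and -0.15 without dexamethasone replicates 1 to 4, fits that tested more of its members, and it was 0.14 and 0.06 without control replicates 3 and 4. The counts of these small lists were the same adjusted over each list alone.

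**Figure D3:**
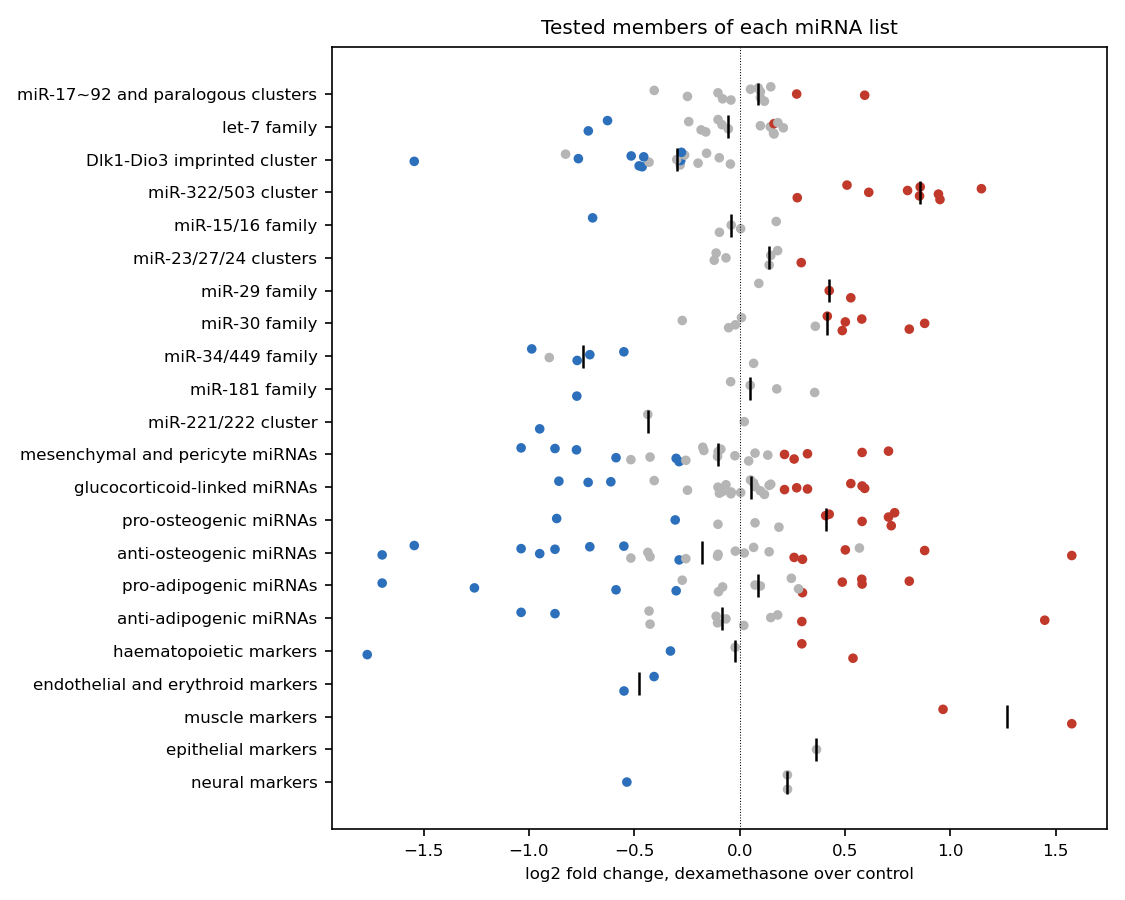
Log2 fold change of dexamethasone over control for each tested arm on the 22 lists, red higher and blue lower at an edgeR adjusted p below 0.05, grey not past it; the black line is the list's median. The 9 arms of the cluster of miR-322 and miR-503 lie above 0 and the 17 of the Dlk1-Dio3 cluster below; with upper quartile scaling the medians of miR-17~92, miR-23, miR-27 and miR-24, miR-181, glucocorticoid-linked and pro-adipogenic miRNAs turn negative.

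Of 53 hairpins with both arms tested, miR-148a was the 1 whose arm ratio passed the limma test, and 13 had an unadjusted p below 0.05. For miR-148a the log2 ratio of 5p to 3p went from -1.23 in control to -2.74 in treated samples (SE of the difference 0.18; limma adjusted p = 0.00106), as miR-148a-5p fell (-1.26 ± 0.13) while miR-148a-3p was at 0.28 ± 0.12 (log2 fold change ± SE, edgeR adjusted p = 0.0781, and 0.0191 without dexamethasone replicate 4). The arms of miR-140 were called in opposite directions by edgeR, miR-140-5p lower (-0.27 ± 0.09) and miR-140-3p higher (0.43 ± 0.12, log2 fold change ± SE, edgeR adjusted p = 0.0286 and 0.00918). The miR-140 ratio missed the threshold (difference -0.68 ± 0.19, SE, limma adjusted p = 0.0821) but passed without dexamethasone replicate 4 (0.0377). Leaving out 1 replicate gave 1 to 5 hairpins, 5 without dexamethasone replicate 1 or 4, 3 without dexamethasone replicate 3, and 2 without control replicate 1 or dexamethasone replicate 2. miR-148a passed in each of these fits, and the others were miR-195, miR-22, miR-30b, miR-30d, miR-324, miR-140, miR-181c and miR-221. Of these, miR-195 and miR-181c were not among the 53 hairpins, as miR-195-3p and miR-181c-5p were under the filter in the full fit. miR-195 passed without control replicate 1 or any 1 dexamethasone replicate. In 36 of the 53 hairpins both arms had the same sign, and of 16 with both arms past the edgeR threshold 15 did. Across hairpins, which are not independent replicates, the arms' log2 fold changes correlated with Pearson r = 0.680 and Spearman rho = 0.617 (permutation p = 1e-05 for both, the smallest that 100000 resamples can give).

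The authors' deposited table carries its own test of dexamethasone against control, with 64 miRNAs higher and 61 lower at an adjusted p below 0.05. Of those 125, 104 also passed in edgeR, all with the same sign; 21 were called only in the authors' deposited table, 11 of them among miRNAs left out by the abundance filter, and 9 only in edgeR. For miR-146a-5p the authors' deposited table gives a log2 fold change of -1.79 and an adjusted p of 2.82e-102, and for miR-672-5p 2.30 and 1.15e-42.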

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

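In 4 of 136 groups of 4 samples (2.94%) a sample lay far from the other 3, where chance gives about 5%. miR-132-3p was at 3520 CPM in control replicate 1, against 3151 to 3169 CPM in the other controls. miR-21-5p was at 63600 CPM in control replicate 2, against 70224 to 71258 CPM in the others. miR-195-5p was at 71.1 CPM in dexamethasone replicate 3, against 94.3 to 95.3 CPM, and miR-34c-5p at 396 CPM in dexamethasone replicate 1, against 461 to 465 CPM.

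The tests of chance, depth and abundant miRNAs for the counts of changed miRNAs were set before their results were seen. Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave 113 miRNAs past the threshold, and the highest of the other splits gave 0. That is the smallest share the splits allow. The other splits put treated and control samples in the same group, which widens the spread within groups. Few calls were therefore likely in them, and the 0 calls do not by themselves exclude chance for that count. For miRNAs also changed 1.5-fold the real split gave 65 and the highest other 0, again 1 of 35. Chance cannot be excluded for the number of lists, where the real split gave 3, the highest other 3 and 7 splits as many, or for the number of hairpins whose arm ratio passed, where the real split gave 1, the highest other 1 and 2 splits as many.

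The shallower treated libraries could have produced the 113 calls. Thinning every library to 1377881 counts gave 101 calls, 98 of them among the 113 (15 lost, 3 gained). This argues against the unequal number of counts as the whole source. Thinning equalizes counts only, so any other difference that goes with the shallower libraries stays in them. The 10 most abundant miRNAs take most counts, and leaving them out of the library sizes gave 117 calls, 108 of them among the 113, which argues against a shift in a few miRNAs as the whole source. A library batch that follows the treatment stays open, since the labels give none, and so does an effect of dexamethasone itself. The sample labels used here give no time in culture and no vehicle for the controls. A difference in either cannot be told apart from the treatment.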

How the results depend on the processing

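No sign changed among the 113 called miRNAs under any alternative to the edgeR fit that tested them, and at the 0.05 threshold calls numbered 97 (replicate block) to 130 (without dexamethasone replicate 4). RLE size factors in edgeR gave 55 higher and 55 lower, upper quartile scaling 41 and 71, and total counts 58 and 55. The DESeq2 Wald test gave 53 and 53, limma voom 62 and 51, no filter 61 and 55, and the stricter filter 49 and 59. Thinning gave 53 and 48, library sizes without the 10 most abundant miRNAs 70 and 47, and a threshold of 0.1 75 and 59. Leaving out 1 replicate gave 50 to 70 higher, 47 to 60 lower and 58 to 69 changed 1.5-fold. Of 65 named miRNAs 45 were called, and 36 of these kept the call in every alternative. Leaving out 1 replicate moved the log2 fold change by over 1.5 times in 1 of these 45, let-7f-5p, and moved or turned it in 16 of the 20 that did not pass (turned in 4: miR-15b-5p, miR-29c-3p, miR-181b-5p and miR-221-5p). Whether samples with the same replicate number are pairs is not given in the labels. Correlations of same-number deviations were -0.03, -0.10, 0.08 and -0.21. They show no clear pairing, but so few values cannot exclude it. With the replicate block 52 were higher and 45 lower, and the 16 lost calls say nothing about effect size.

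With an estimated correlation camera lost the miR-322 and miR-503 and Dlk1-Dio3 clusters (adjusted p = 0.180 each) and the miR-34 and miR-449 family (0.349). The estimated correlations were 0.0493, -0.00618 and 0.0753, against the preset 0.01. For Dlk1-Dio3 the estimate lay below the preset value, which argues against correlation among its members as the cause of that loss. camera also takes fewer degrees of freedom when it estimates the correlation, which raises p by itself. The losses are therefore no sign that list members move together. The 2 effects were not separated for the other 2 lists. Leaving out 1 replicate gave camera adjusted p of 0.000795 to 0.00169, 0.0126 to 0.0610 and 0.0320 to 0.0797 for these lists. fry, which asks another question, gave adjusted p = 0.00242 for miR-29, 0.00180 for miR-30, 0.000827 for miR-221 and miR-222, 0.00401 for the mesenchymal, 0.00118 for the pro-osteogenic, 0.00227 for the anti-osteogenic, 0.0350 for the pro-adipogenic and 0.000319 for the haematopoietic list. Hairpins whose arm ratio passed numbered 1 to 5 leaving out 1 replicate. Part of this range comes from miR-195 and miR-181c, which were not tested in the full fit, and the cause of the rest was not tested.

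The difference in library size was -961822 to -693905 counts leaving out 1 replicate. Without any 1 treated sample (differences -821738, -845977, -812554 and -798102 for replicates 1 to 4) the exact permutation p was 0.0571, as 1 other assignment gave a difference as large in size. The difference in miRNAs with at least 10 counts was -20.25 (exact permutation p = 0.0286), while the difference at 1 count was -8.75, and 4.75 after thinning, so depth limits counts of detected miRNAs. The alternatives for normalized values were not run, as the table holds counts, nor the restriction to miRBase names, which all 487 miRNAs carry.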

Other observations

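The tests on miR-146a-5p and on neighbouring genes were chosen after the results were seen. Several miRNAs outside the lists rose or fell too. rno-miR-101a-3p rose with miR-101b-3p, from 198 ± 15.4 to 282 ± 27.8 CPM (SD, n = 4, edgeR adjusted p = 8.04e-04), though reads can be shared between these near-identical miRNAs. From the X-linked miR-532 cluster miR-500-3p (from 5.92 ± 0.821 to 11.9 ± 3.77 CPM) and miR-362-3p (from 4.34 ± 1.08 to 8.52 ± 2.19 CPM) rose with miR-532-5p (edgeR adjusted p = 0.00983, 0.0193 and 1.54e-05), while the other tested arms, miR-532-3p, miR-501-3p and miR-362-5p, were at 0.51 ± 0.20, 0.51 ± 0.22 and 0.52 ± 0.43 (log2 fold change, SE, edgeR adjusted p = 0.0563, 0.0799 and 0.368). rno-miR-191a-5p and rno-miR-425-5p, within the same host gene, both rose (0.42 ± 0.10 and 0.39 ± 0.11, log2 fold change ± SE, edgeR adjusted p = 0.00412 and 0.00983). rno-miR-196a-5p fell from 10006 ± 97.2 to 7161 ± 247 CPM and rno-miR-340-5p from 176 ± 10.5 to 102 ± 3.12 CPM (SD, n = 4, edgeR adjusted p = 3.00e-05 and 1.97e-05). These miRNAs were chosen after their values were seen.

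The largest fitted rises were in miRNAs nearly absent from controls. miR-592 had 5 counts over the 4 controls and 54 over the 4 treated samples, and miR-326-3p 12 and 82, with log2 fold changes of 3.95 ± 0.50 and 3.38 ± 0.34 (SE, edgeR adjusted p = 3.54e-05 and 7.20e-06). Among muscle miRNAs outside the filter, miR-1-3p had 20 counts in control and 40 in treated samples, and miR-133a-3p 11 and 27, and both passed with no filter (edgeR adjusted p = 0.00999 and 0.0117). Both pairs were chosen after their values were seen.

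The fall of miR-146a-5p may be a response within the cells or a loss of haematopoietic cells, which bone marrow cultures can hold. The other 4 tested haematopoietic markers had a median log2 fold change of 0.137 (SD 0.377) against -1.77 for miR-146a-5p, which argues against such a loss as the cause. A change within the remaining cells, through dexamethasone or otherwise, stays open and was not tested.

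Neighbouring miRNA genes differed less in log2 fold change than permuted pairs did. Outside the families and clusters tested as lists, 19 pairs of hairpins within 10 kb (11 clusters among 109 hairpins) differed on average by 0.261 in log2 fold change, against 0.808 for permuted pairs (permutation p = 0.00011, one-sided, 100000 resamples). Values were permuted over all 109 hairpins, those without a neighbour included. A smaller spread of changes among clustered hairpins could therefore also give a small p, and values were not permuted among clustered hairpins alone. miR-132-3p with miR-212-5p and miR-191a-5p with miR-425-5p are neighbouring pairs of this kind. Their values and those of the miR-532 cluster had been seen before the test was chosen, so the test is not independent of them. With each cluster left out in turn the largest permutation p was 0.00059, which argues against a single cluster carrying the result. The clusters seen before were not left out together. Control through shared primary transcripts is a candidate explanation; a likeness in abundance between neighbours was not tested, and hairpins are not independent replicates.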
